A study of Caenorhabditis elegans with 8 samples.

How the data were processed

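RNA of whole worms was sequenced from 8 samples, 4 exposed to DMSO and 4 to 50 µM zidovudine for 24 h. Per the labels' protocols, RNA was extracted with a column kit, mRNA was captured on oligo-dT beads, libraries were made with a directional kit, and sequencing was done on a NovaSeq instrument. Oligo-dT capture favours polyadenylated RNA, so mRNAs with short or no poly(A) tails are measured less reliably. Per the labels' descriptions, DMSO 4 came from another flow cell than the other 7 libraries.

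The authors deposited 1 table of 17826 genes with 1 column per sample. Per the file headers the columns are CPM, but they hold negative values, and the deposited values are log2 CPM. The submitters' processing notes name FastQC, Trimmomatic 0.32, HISAT2 2.1.0, HTSeq 0.11.0, edgeR 3.26.8 and limma 3.40.6 without their roles. The genome build, the annotation and whether reads were counted by strand are not given in the sources used here. The lowest value, -4.39, is the same in all 8 columns. On the linear scale, each value minus the floor was a whole multiple of 1 step per column, for 100% of the values within 0.05 reads. This gave the number of reads behind each value and a prior of 2 reads at the mean effective library. The effective library was 0.973 to 1.03 times the total. The added prior pulls the fold changes of genes with few reads toward 0.

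Gene names came from the file. For 11 genes the symbol had been turned into a date, and these symbols were restored through the gene ID. The reference name table held 16949 of the IDs. Positions and exon lengths were taken by gene ID from Ensembl release 115 on the build WBcel235; lengths are the union of exons and were found for 12376 of the 12382 tested genes.

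The main test was limma-trend (limma 3.58.1 in R 4.3.3, robust empirical Bayes, two-sided) on the deposited log2 CPM of genes with a mean of at least 0, with the group as the only term, which left 6 residual degrees of freedom. The design had been written for count tables with limma-trend as the stated choice for log2 values. Since the unit was log2, limma-trend was used. P-values were adjusted by Benjamini and Hochberg's method over the 12382 genes, with a threshold of 0.05. A difference or log2 fold change is zidovudine minus DMSO. The 43 gene lists, made up of pathways, gene families and cell type markers, were tested with camera in limma with a preset correlation of 0.01 against all other genes, adjusted over the 43 lists. Lists needed at least 5 tested members. The members of a list were also adjusted over the list alone. Intervals of list means are 95% intervals from the spread of the 4 libraries in each group. The design, the lists, the rule for named genes and most of the other settings tried were fixed before the data were examined.

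Named genes were, in each direction, up to 12 genes with the largest fold change among those past the threshold with a mean of at least 1 log2 CPM and no overlap between groups. For each list, up to 4 members past the threshold were named, or else the member with the smallest p. A set of genes tied to the drug or to the study's subject was named whatever its result. There were 70 such genes, counting asm-3 and dhs-26, which passed the threshold below 1 log2 CPM. hsp-16.2 also passed below 1 log2 CPM and was named as a member of its lists. Some of the members that passed when adjusted over a list alone, and some mitochondrially encoded genes, were also named, after their values were seen.

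The depth was 30449021 to 56930820 reads assigned to genes per library. Replicates differed by far more than sampling noise, with a chi-square of 17.5 to 88.2 per degree of freedom between libraries of a group, so no library was a repeat sequencing of another. This does not show that the libraries came from separate RNA samples. The scripts were tested on simulated data with the means and spread of the 12382 genes in 4 and 4 libraries. The test recovered 60% of 50 genes changed 1.5-fold, 70% of 50 changed 2-fold, 92% of 50 changed 3-fold and all 50 changed 4-fold, with 7 false calls among 168. The simulated genes varied independently of each other, with no trend on gene length and no library set apart. More genes also passed than the 21 of the real data, which eases the adjusted threshold. These shares therefore need not hold for the real data.

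Alternatives were quantile normalization, limma without trend, no filter, a filter at 1 log2 CPM, the replicate number as a block, sample quality weights, leaving out each library, stricter thresholds, and for lists an estimated correlation, a rank-based camera and the self-contained fry test. Added after seeing the data were voom on the recovered reads, a prior of 0.5 reads, library totals as the only scaling, the main component of the residuals as a covariate, removal of each library's trend on gene length, and leaving out DMSO 4 together with zidovudine 2, the libraries that deviated most from their groups.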

Results

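The polyadenylated RNA of whole Caenorhabditis elegans was sequenced after exposure to zidovudine or to the DMSO vehicle. Zidovudine is an antiretroviral drug, a thymidine analogue that inhibits reverse transcriptase. Wild-type worms (strain N2) were moved at larval stage 4 to plates with 50 µM zidovudine or DMSO and harvested 24 h later, on day 1 of adulthood. The treatment protocol, worded alike for all 8 samples, says that plates also held 5-fluorouracil, a pyrimidine analogue, and was taken to apply to both groups. Each group had 4 samples, and each sample gave 1 library. The labels do not say whether the samples came from separate cultures, so p-values measure the spread between these samples. The values were log2 CPM, reads scaled to library size, for 17826 genes. The libraries held 30449021 (DMSO 3) to 56930820 (zidovudine 1) reads assigned to genes. DMSO 4 was sequenced on another flow cell than the other 7 libraries, so the flow cell cannot be separated from that library, and values without it are values within 1 flow cell. It listed 1469 genes with 0 reads, 8.24% of all, against 1.07% to 2.17% in the other libraries.

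The series' title names changes in pyrimidine metabolism, lower translation and the transcription factor ATF-4 as its subject, and the comparison of zidovudine with DMSO asks which mRNAs moved with the drug. Of 12382 genes tested, 7 were higher and 14 were lower with zidovudine (limma, adjusted p under 0.05). At an unadjusted p under 0.05 there were 1457 genes, where chance gives 619 on average. Genes vary together and the spread of that number was not measured, so the excess is not a test. Leaving out 1 library gave 920 (without zidovudine 3) to 2190 (without zidovudine 2). The clearest decrease was that of F42A10.7 (WBGene00018343; chromosome III, 6177916 to 6178686 in WBcel235, protein coding). It went from 4.65 ± 0.16 log2 CPM with DMSO to 3.37 ± 0.11 with zidovudine (SD, n = 4 each), a 2.43-fold decrease (log2 fold change -1.28, SE 0.11, limma adjusted p = 3.81e-05). The clearest increase was that of T05E12.6 (WBGene00011487; chromosome V, 17085002 to 17089442), 1.38-fold, from 6.76 ± 0.063 to 7.23 ± 0.070 log2 CPM (log2 fold change 0.47, SE 0.061, limma adjusted p = 0.00394). arrd-24, an arrestin domain gene on the X chromosome, rose 2.54-fold (log2 fold change 1.34, SE 0.21, limma adjusted p = 0.0245). The other genes that rose were T03F1.6 (log2 fold change 0.85), F35E12.6 (0.50), tag-10 (0.42), folt-2 (0.41), which encodes a folate-like transporter, and sto-1 (0.40), which encodes a stomatin.

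The genes that fell included those for the chaperones HSP-70 (hsp-70, log2 fold change -1.16, SE 0.19) and HSP-16.2 (hsp-16.2, -1.56, SE 0.29), the C-type lectin clec-52 (-0.73), ule-2, whose product is found in the uterine lumen (-0.67), the putative serine protease pcp-1 (-0.42) and the mitochondrially encoded cytochrome c oxidase subunit ctc-3 (-0.50). F19B10.13 (-0.93), Y48E1B.8 (-0.67), Y57G11B.5 (-0.60), K11D12.13 (-0.56) and D1086.10 (-0.47) also fell. With the trend of each library on gene length removed, F19B10.13, K11D12.13 and hsp-16.2 missed the threshold. Across the other settings F19B10.13 ranged from -1.07 to -0.52. Among the 21 genes past the threshold, the lowest fold changes were those of asm-3, a putative sphingomyelinase gene (-2.40, SE 0.29, limma adjusted p = 0.00315), and dhs-26, a short-chain dehydrogenase gene (-2.20, SE 0.29, limma adjusted p = 0.00394). Both have a mean under 1 log2 CPM, outside the rule for named genes, and were named after their values were seen. asm-3 had 13 to 120 reads per library and dhs-26 24 to 192. In all 21 genes the 4 zidovudine libraries lay on one side of the 4 DMSO libraries. Over all tested genes this held for 824, or 6.65%, where chance gives 2.86% on average. Of the 21 genes, 6 overlap a gene on the opposite strand. Among them hsp-70 shares 2195 nt with uggt-2, so its value is uncertain, because it is not stated whether counting used the strand.

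**Figure D1:**
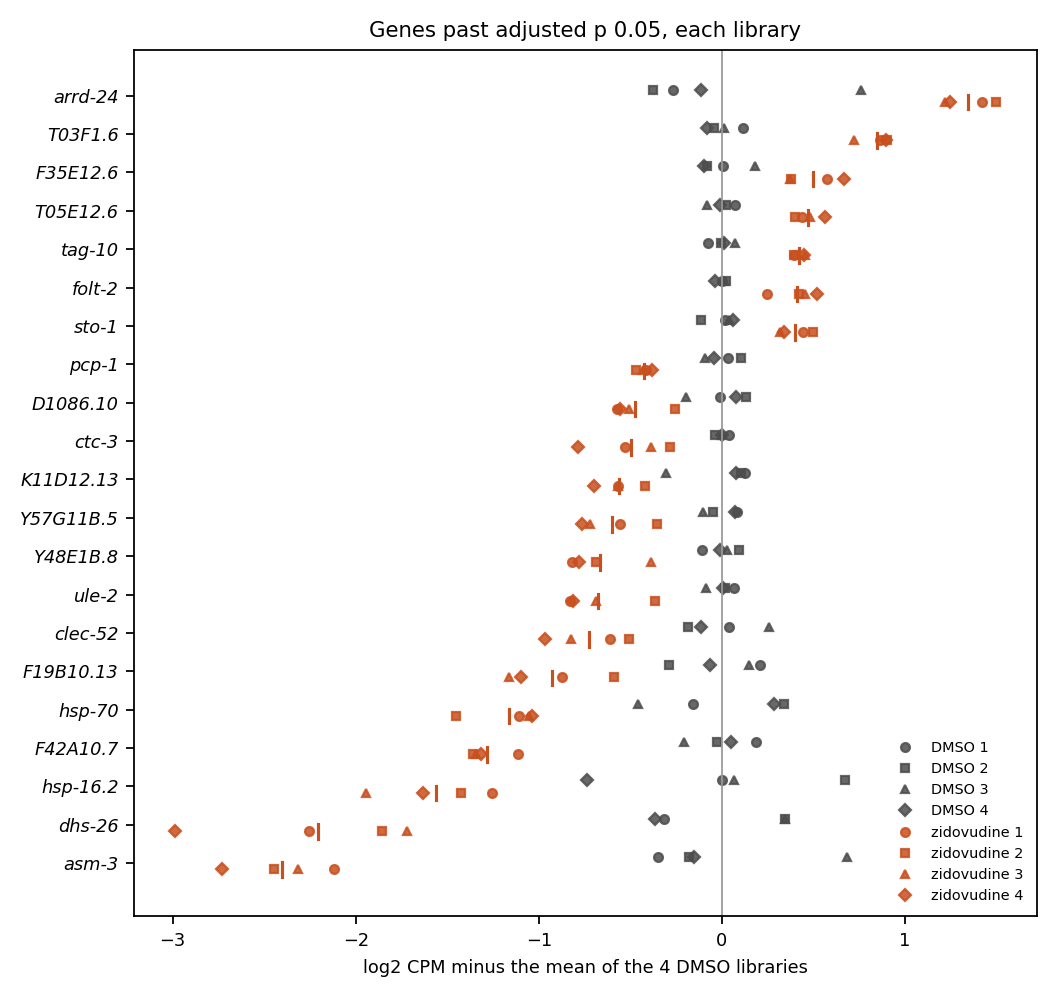
Each line is 1 of the 21 genes past the threshold, and each symbol is 1 library, placed at its log2 CPM minus the mean of the 4 DMSO libraries (x axis); vertical bars mark the mean of the 4 zidovudine libraries. The zidovudine libraries are all below the DMSO libraries for 14 genes and all above them for 7, from asm-3 at -2.40 to arrd-24 at 1.34.

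With sample quality weights 74 genes were higher and 74 lower, all 21 among them. With quantile normalization 6 genes were higher and 7 lower, and with library totals as the only scaling 5 were higher and 7 lower. Leaving out 1 library at a time gave 1 to 17 genes higher and 3 to 28 lower; F42A10.7, asm-3, T05E12.6 and dhs-26 stayed past the threshold each time, and each of the other 17 genes lost its call without at least 1 library.

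Genes chosen beforehand for their relation to the drug or the study's subject did not pass the threshold. Since the plates of both groups were taken to hold 5-fluorouracil, a pyrimidine analogue, these values compare zidovudine with DMSO in its presence. The transcript of the transcription factor ATF-4, listed in the file under its older symbol atf-5, was at 5.53 ± 0.14 log2 CPM with DMSO and 5.41 ± 0.23 with zidovudine (SD, n = 4 each; log2 fold change -0.12, 95% interval -0.35 to 0.11, limma adjusted p = 0.671). The differences were 0.070 for atfs-1, the regulator of the mitochondrial unfolded protein response, 0.075 for its target hsp-6, and 0.0098 for the endoplasmic reticulum chaperone hsp-4. They were 0.091 for the thymidylate synthase tyms-1, 0.061 for umps-1, 0.031 for dut-1 and 0.14 for the ribonucleotide reductase rnr-1. They were 0.010 for polg-1, the mitochondrial DNA polymerase, -0.16 for hmg-5, -0.058 for gst-4 and 0.13 for sod-3. The limma adjusted p of these genes ran from 0.487 for rnr-1 to 0.971 for polg-1. The pyrimidine metabolism list had 15 members above 0 and 10 below, with a median log2 fold change of 0.019 and none past the threshold (camera adjusted p = 0.847). The difference between the groups' list means was -0.0021, with a 95% interval over libraries of -0.061 to 0.056. Of the 29 members of the ATF-4 and integrated stress response list, 14 were above 0 and 15 below, with a median of -0.012 (camera adjusted p = 0.864) and a difference of list means of 0.0077 (-0.044 to 0.060). The mitochondrial unfolded protein response list (19 members, median 0.034, camera adjusted p = 0.884) did not pass either. In these 3 lists the median and the mean differ in sign.

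The mRNAs encoded by the mitochondrial genome were lower with zidovudine. All 11 tested members of that list were below 0, with a median log2 fold change of -0.53 (camera adjusted p = 1.70e-14). The call was lost with an estimated correlation between genes (adjusted p = 0.167 with an estimated correlation, unadjusted p = 0.00388). These genes encode subunits of respiratory chain complexes and of the ATP synthase. All 11 passed when adjusted over the list alone, and 1, ctc-3 (WBGene00010962; MtDNA, 5678 to 6449), passed over all genes tested. That call was lost in 12 of 20 other settings, among them quantile normalization and a filter at 1 log2 CPM. ctc-3 went from 9.77 ± 0.031 to 9.28 ± 0.22 log2 CPM (SD, n = 4 each; limma adjusted p = 0.0459), with at least 22846 reads in each library. The ATP synthase subunit atp-6 was at -0.58 (SE 0.12), the complex I subunit nduo-1 at -0.53 (SE 0.11) and the cytochrome b gene ctb-1 at -0.34 (SE 0.11). The values furthest from 0 were those of nduo-3 (-2.22, SE 0.60) and nduo-6 (-2.06, SE 0.61), which had the fewest reads, with 41 in zidovudine 2 for nduo-3 and 64 for nduo-6, and which were also highest in DMSO 4. Together the list took 0.785% to 0.876% of the reads with DMSO and 0.496% to 0.673% with zidovudine. The list mean was lower in every zidovudine library than in every DMSO library (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give, 0.154 after adjustment over the 43 lists). Other lists reached the same p, as given below. Without DMSO 4 the median was -0.49.

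**Figure D2:**
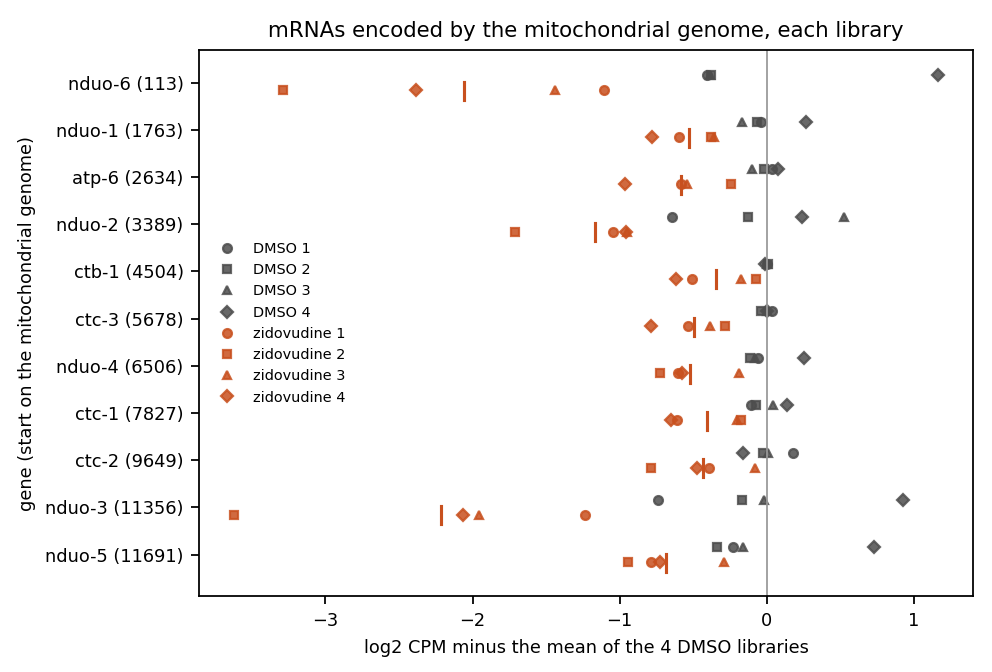
Each line is 1 of the 11 tested genes of the mitochondrial genome, in the order of their start positions, and each symbol is 1 library, placed at its log2 CPM minus the mean of the 4 DMSO libraries (x axis); vertical bars mark the mean of the 4 zidovudine libraries. All 11 bars lie below 0, from -0.34 for ctb-1 to -2.22 for nduo-3.

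Ribosomal protein mRNAs were lower as lists, by smaller amounts and not in every setting. Of the 82 cytosolic ribosomal protein genes tested, 79 were below 0, with a median log2 fold change of -0.14 (camera adjusted p = 8.79e-09; adjusted p = 0.725 with an estimated correlation). Of the 72 mitochondrial ribosomal protein genes, 69 were below 0, with a median of -0.16 (camera adjusted p = 6.76e-14; adjusted p = 0.36 with an estimated correlation). The ribosome biogenesis list had 34 of 40 members below 0 (median -0.075, camera adjusted p = 7.65e-05), and the nuclear-encoded oxidative phosphorylation list had 50 of 69 below 0 (median -0.11, camera adjusted p = 0.000593). With an estimated correlation the adjusted p of the last 2 lists was 0.725, so none of these 4 calls held. No member of these 4 lists passed by itself, over all genes or adjusted over the list alone. The members with the smallest p were rpl-22 at -0.33, mrpl-13 at -0.36, the ribosomal RNA processing gene rrp-1 at -0.20 and Y53G8AL.2 at -0.15. The lists of translation factors (46 members, median -0.030, camera adjusted p = 0.0812) and aminoacyl-tRNA synthetases (32 members, median -0.013, camera adjusted p = 0.847) did not pass.

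The libraries differed in the level of short mRNAs. The 678 tested genes with under 500 nt of exon had a median log2 fold change of -0.34 and the 375 genes with 5000 nt or more one of 0.11, and the Spearman correlation of fold change with length was 0.366 across genes, which are not independent replicates. The difference was not shared by all zidovudine libraries, since the genes under 500 nt deviated by a median of 0.80 in zidovudine 2 and of -0.62 in zidovudine 4 from the other libraries of the group. The median exon length was 521.5 nt for the cytosolic ribosomal protein list, 767 nt for the mitochondrial one and 1438 nt for all tested genes. With the trend of each library on length removed, a setting chosen after seeing the data, the cytosolic list was at 0.024 (camera adjusted p = 0.544), the mitochondrial one at -0.078 (2.06e-05), ribosome biogenesis at -0.093 (1.87e-07) and nuclear-encoded oxidative phosphorylation at -0.0063 (0.901). Aminoacyl-tRNA synthetases were lower in that setting alone (-0.045, camera adjusted p = 0.0205). Translation factors were lower in it (-0.043, camera adjusted p = 0.00961) and in 5 other settings of 19, among them quantile normalization and leaving out DMSO 1, zidovudine 3 or zidovudine 4. Camera p-values with the trend removed rest on the preset correlation of 0.01. With the trend in place the estimates were 0.22 for ribosome biogenesis and translation factors and 0.39 for aminoacyl-tRNA synthetases. With it removed, the interval of the mean's difference included 0 for ribosome biogenesis (-0.25 to 0.0014). It also did for translation factors (-0.13 to 0.033) and the synthetases (-0.093 to 0.0088). For the mitochondrial list it lay below 0 (-0.15 to -0.017). Without DMSO 4 the medians were -0.084 for the cytosolic list and -0.043 for oxidative phosphorylation, which then missed the threshold (camera adjusted p = 0.0584), and without DMSO 1 the cytosolic median was -0.22. The ribosome biogenesis list missed the threshold without DMSO 4 and zidovudine 2 together (median -0.047).

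**Figure D3:**
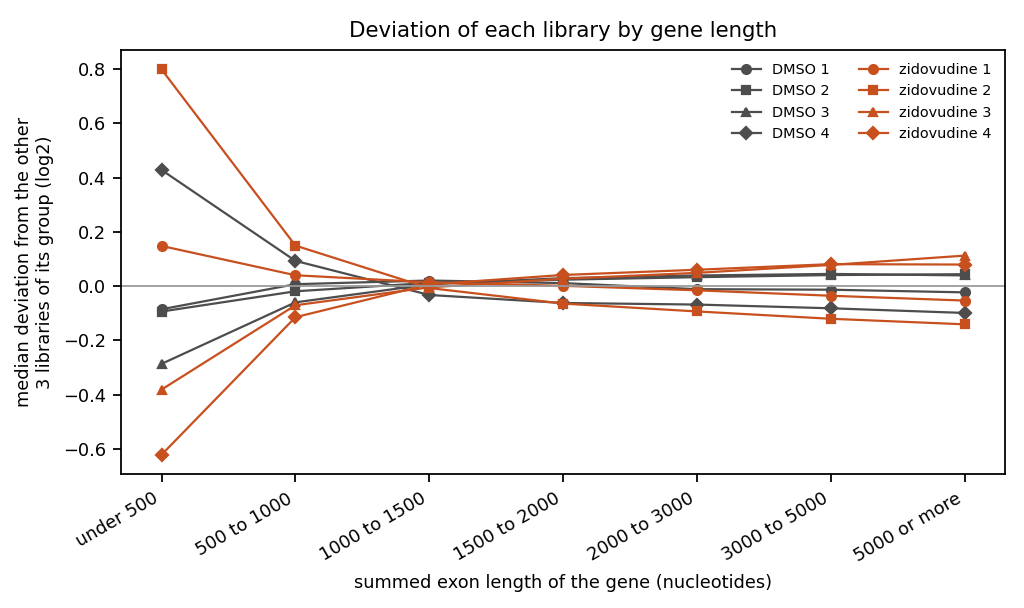
Median deviation of each library from the other 3 libraries of its group on the log2 scale (y axis) for genes grouped by summed exon length in nucleotides (x axis); each line is 1 library. For genes under 500 nt the medians spread from -0.62 in zidovudine 4 to 0.80 in zidovudine 2, with DMSO 4 at 0.43; they come together at 1000 to 1500 nt and spread again at longer lengths, from -0.14 in zidovudine 2 to 0.11 in zidovudine 3 at 5000 nt or more.

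Some heat shock genes were lower. Of 20 tested members of the cytosolic heat shock list, 15 were below 0, with a median log2 fold change of -0.044 and a mean of -0.32 (camera adjusted p = 0.00165; adjusted p = 0.36 with an estimated correlation). hsp-70 and hsp-16.2 passed over all genes, but hsp-70 lost its call in 8 of 20 other settings and hsp-16.2 in 13 of 19. hsp-16.2 had a mean of 0.68 log2 CPM and 31 to 155 reads per library. hsp-16.41 (-1.16, SE 0.25), the Hsp70 gene F44E5.4 (-0.83, SE 0.29) and the small heat shock gene hsp-43 (-0.23, SE 0.075) passed when adjusted over the list alone, 5 members in all. F44E5.4 has a close copy, F44E5.5, with which reads can be shared, so its value is uncertain. The endoplasmic reticulum unfolded protein response list was higher, with 28 of 34 members above 0 and a median of 0.070 (camera adjusted p = 0.00240; adjusted p = 0.725 with an estimated correlation). No member passed by itself; the smallest p was that of the disulfide isomerase pdi-2 at 0.23. The autophagy and lysosome list had 39 of 54 members above 0 (median 0.078, camera adjusted p = 0.00397; adjusted p = 0.725 with an estimated correlation), of which the cysteine protease gene cpr-1 passed when adjusted over the list alone (0.48, SE 0.092). The heat shock median was -0.090 without DMSO 1, -0.076 without zidovudine 1 and -0.070 without zidovudine 4, and that of the endoplasmic reticulum list was 0.039 without zidovudine 4.

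Several lists of tissue markers differed between the groups. All 14 tested pharynx markers were above 0, with a median of 0.32 (camera adjusted p = 1.02e-06; adjusted p = 0.270 with an estimated correlation), and 6 passed when adjusted over the list alone, among them the myosin heavy chains myo-2 (0.41, SE 0.086) and myo-1 (0.48, SE 0.11) and the transcription factor gene pha-4 (0.34, SE 0.11). All 7 tested members of the eggshell and late embryo cuticle list were above 0, with a median of 0.45 (camera adjusted p = 9.23e-08; adjusted p = 0.270 with an estimated correlation), and 6 passed when adjusted over the list alone. They were fbn-1 (0.45), sym-1 (0.46), hch-1 (0.67), noah-1 (0.28), noah-2 (0.30) and Y47D3B.6 (0.95). fbn-1, noah-1 and noah-2 encode proteins of the apical extracellular matrix of the epidermis and hch-1 encodes the hatching enzyme. Which tissue or stage within the whole worms these mRNAs came from was not tested. Of 27 neuronal markers 22 were above 0 (median 0.11, camera adjusted p = 0.000267; adjusted p = 0.270 with an estimated correlation). The intestine list had 19 of 24 members above 0 (median 0.17, camera adjusted p = 0.00250; adjusted p = 0.725 with an estimated correlation), and its median was 0.11 without zidovudine 4. Adjusted over the list alone, cpr-1, lgx-1, ifd-2 and ifc-2 were higher, and the ferritin gene ftn-1 (-1.06, SE 0.22) and the desaturase gene fat-7 (-0.27, SE 0.082) were lower. None of these members passed over all genes.

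Germ line lists went in different directions. The oocyte and maternal list had 31 of 32 members above 0, with a median of 0.084 (camera adjusted p = 0.00114; adjusted p = 0.814 with an estimated correlation). It lost its call without zidovudine 4 (median 0.044, camera adjusted p = 0.0947), and its median was 0.051 without DMSO 4. The sperm list had 65 of 71 members below 0, with a median of -0.38 (camera adjusted p = 3.56e-14; adjusted p = 0.36 with an estimated correlation). Adjusted over the list alone, 8 sperm genes were lower, among them msd-2 (-0.70, SE 0.16) and msp-36 (-0.50, SE 0.13), and spe-41 was higher (0.38, SE 0.11). Across the other settings msd-2 ranged from -0.77 to -0.26. The msp genes, for the major sperm protein, are near-identical copies between which reads can be shared, so their values are uncertain. The sperm list has a median exon length of 384 nt, and with the length trend removed its median was -0.14 (camera adjusted p = 0.00121). The proliferating and meiotic germ line list had a median of -0.0082 over 33 members and did not pass (camera adjusted p = 0.488), but with the length trend removed it was lower (-0.035, camera adjusted p = 0.00980). The DNA replication and cell cycle list had 38 of 52 members above 0 (median 0.040, camera adjusted p = 0.0358; adjusted p = 0.814 with an estimated correlation). It missed the threshold without DMSO 1 (0.023), DMSO 4 (0.025), zidovudine 3 (0.018) or zidovudine 4 (0.019), with quantile normalization (0.033) and with the length trend removed (0.020), and its median was 0.065 without DMSO 2 and 0.070 without zidovudine 2.

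Of the collagen genes tested, 28 were above 0 and 87 below, with a median of -0.11 (camera adjusted p = 0.00114; adjusted p = 0.814 with an estimated correlation). The list missed the threshold without DMSO 4 (median -0.031, camera adjusted p = 0.725) and without zidovudine 3 (median -0.076), as well as without DMSO 4 and zidovudine 2 together (-0.019), and without DMSO 1 the median was -0.18. Of 43 ABC transporter genes 33 were above 0, with a median of 0.075 (camera adjusted p = 0.00990; adjusted p = 0.725 with an estimated correlation). pgp-14 (0.62, SE 0.12) and abt-2 (0.37, SE 0.087) passed when adjusted over the list alone. The ABC transporter list missed the threshold without DMSO 4 (median 0.037), without zidovudine 4 (0.022) and with the length trend removed (0.012), and its median was 0.049 without zidovudine 3. Together 9 of the 43 lists were higher and 8 lower. None of these calls held with an estimated correlation after adjustment over the lists, and 4 lists, those of mitochondrially encoded genes, eggshell and late embryo cuticle, neurons and pharynx, had an unadjusted p under 0.05 in that test. The exact permutation p of 0.0286 of the mitochondrially encoded list was shared by the endoplasmic reticulum, heat shock, autophagy, eggshell and neuron lists. Mitochondrial DNA maintenance and DAF-16 targets, which were not called, also reached it. The exact permutation p was 0.0571 for ribosome biogenesis, sperm and pharynx and 0.0857 for mitochondrial ribosomal proteins. For the other called lists it ran from 0.257 (DNA replication) to 0.457 (collagens).

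**Figure D4:**
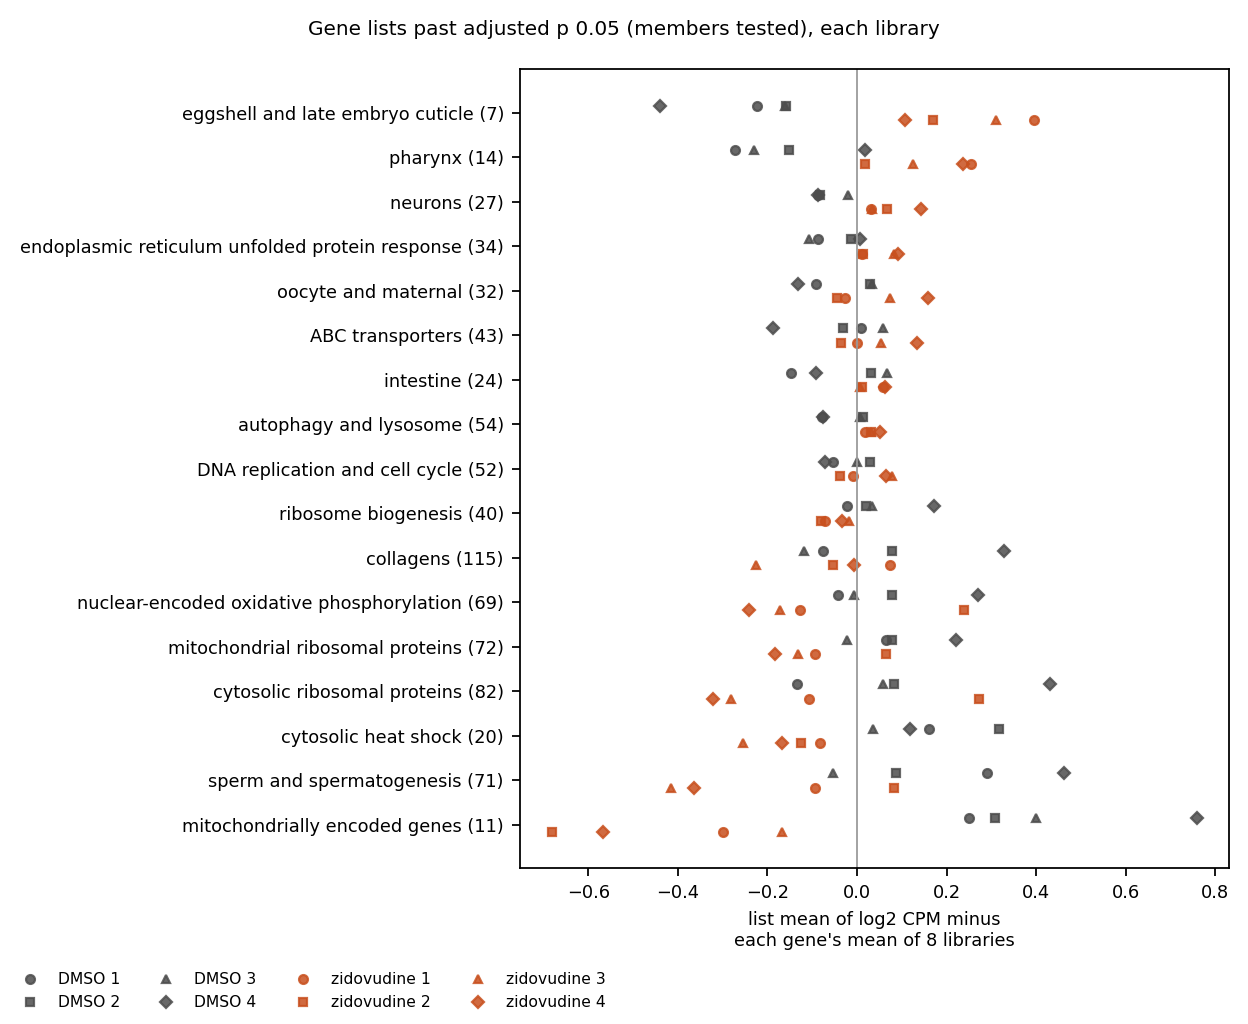
Each line is 1 of the 17 gene lists past the threshold, with the number of members tested, and each symbol is 1 library, placed at the mean over members of log2 CPM minus each gene's mean over the 8 libraries (x axis). The mitochondrially encoded list averages 0.43 in the DMSO libraries and -0.43 in the zidovudine libraries with no overlap, while for cytosolic ribosomal proteins DMSO 4 at 0.43 and zidovudine 2 at 0.27 are the 2 highest libraries.

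Body wall muscle (24 members, median 0.076, camera adjusted p = 0.0543), hypodermis (22, 0.048, 0.136), early embryo (23, 0.031, 0.488) and gonad sheath, uterus and coelomocyte markers (11, 0.073, 0.847) did not pass. Body wall muscle was near the threshold and passed in 8 of 19 other settings, up to a median of 0.14 without DMSO 4 and zidovudine 2 together, but its median was 0.018 with the length trend removed (camera adjusted p = 0.535), where it did not pass. Nor did the lists for detoxification, with medians of 0.054 for cytochrome P450s, 0.085 for UDP-glucuronosyltransferases, -0.015 for glutathione S-transferases and 0.0055 for SKN-1 and oxidative stress. Vitellogenins were at 0.041, purine metabolism at 0.019, fatty acid metabolism at 0.042, the proteasome at -0.0062, DNA damage response and repair at 0.0017, and maintenance and transcription of mitochondrial DNA at -0.052. C-type lectins were at 0.034, antimicrobial effectors at -0.23, the intracellular pathogen response at -0.019, neuropeptides at -0.032, histones at 0.011 and DAF-16 class I targets at 0.041. The antimicrobial median went to -0.0017 with the length trend removed, and the list was lower in 3 of 19 other settings, each of them without zidovudine 2 or with the residual component as a covariate. The proteasome list was lower in 4 of 19 other settings, to a median of -0.052 without DMSO 1, and the neuropeptide list was lower without zidovudine 2 (median -0.14). UDP-glucuronosyltransferases were higher without DMSO 1 (median 0.12) and hypodermis markers without zidovudine 4 (0.041). The mean of the DAF-16 list was -0.28, the opposite sign of its median, and its members that passed when adjusted over the list alone were hsp-16.2 and hsp-16.41, which the heat shock list also holds.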

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

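Of the tests reported here, those on the 10 most abundant genes and on the flow cell were chosen only after the result was seen. Removal of the length trend was also a setting added after the data were seen. In 112 groups of 4 libraries, 8 held a library whose gap to the nearest other took up most of the group's range, where chance alone would give about 1 in 20 groups, or 5.6.

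DMSO 4 stood apart in 2 measures, as 8.24% of its genes had 0 reads, against 1.25% to 2.17% in DMSO 1 to 3, and its mean correlation with the other libraries of its group was 0.984, against 0.98967 to 0.99062. A trend of this library on gene length is not the whole of it, because with the trend removed the SD of its deviation from its group was 0.40, above the highest of the other 7 libraries, 0.29. A few genes taking most of the reads would need an unusual share, and its 10 most abundant genes took 8.55%, within the 7.38% to 10.5% of the others. Low complexity of the library may account for it: among 719 genes with a mean of at least 8 log2 CPM its SD was 0.22, under the 0.27 of zidovudine 2 though above the 0.095 to 0.20 of the other 6, and 354 genes had 0 reads there although at least 10 were expected, against 0 to 18 in the others. The other flow cell cannot be told apart from the library itself, since the flow cell holds 1 library; its label alone also carries an R after the library number, whose meaning is not given in the sources used here, and no biological explanation was tested.

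The mean of the neuron list was highest in DMSO 3, at -0.020, with the other DMSO libraries at -0.087 to -0.082. F42A10.7 was highest among the zidovudine libraries in zidovudine 1, at 3.54 log2 CPM, with the others at 3.29 to 3.33. hsp-70 was lowest in zidovudine 2, at 1.13 log2 CPM, with the others at 1.48 to 1.55. K11D12.13 was lowest among the DMSO libraries in DMSO 3, at 4.80 log2 CPM, with the others at 5.18 to 5.24. tyms-1 and atfs-1 were lowest in DMSO 1, at 6.37 and 6.72 log2 CPM, with the others at 6.45 to 6.47 and 6.81 to 6.82.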

How the results depend on the processing

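The recovered-read, residual-component, length and outer-library settings were chosen after the result was seen. Against 7 genes higher and 14 lower, planned settings gave 2 and 2 without the trend, 1 and 8 with the replicate block, 74 and 74 with quality weights, 1 and 4 at an adjusted p under 0.01, and 1 and 5 at a 2-fold minimum; the last pair only narrows the same calls. Quantile normalization left 7 genes lower and a filter at 1 log2 CPM 8. Of settings chosen after seeing the data, library totals left 7 genes lower, the residual component as a covariate gave 182 and 310, and leaving out DMSO 4 with zidovudine 2 gave 49 and 107. Removing the length trend gave 10 higher, with 7 of the main calls among them, and 16 lower, with 11 of the main calls among them. The quality weights and the residual component kept all 21 genes. That component came from the residuals of the same group fit, so it left fold changes as they were and took out spread within groups. More calls, the 21 among them, largely follow from this and are no support for them. For the other settings the cause of the differences in count was not tested. Leaving out 1 library gave 1 to 17 higher and 3 to 28 lower. F42A10.7 passed under all 20 alternatives run for it and asm-3 under all 19; T05E12.6 and dhs-26 missed the threshold without the trend (limma adjusted p = 0.128 for both). No named gene changed direction and call together. Against 9 lists higher and 8 lower, an estimated correlation in camera left 0 and 0, with 4 lists at an unadjusted p under 0.05, and fry left 3 and 1. With the length trend removed, cytosolic ribosomal proteins went to a median of 0.024, histones to 0.26 (camera adjusted p = 0.000228) and neuropeptides to 0.097 (camera adjusted p = 0.0161); the cause was not tested for histones and neuropeptides. Replicate numbers did not pair the samples: the correlations of deviations were 0.067, -0.18, 0.14 and -0.32 for numbers 1 to 4, and only DMSO 1 matched its own number best. Settings meant for count tables, pseudocounts for linear values and a surrogate variable were not run. Depth limits genes with few reads, such as asm-3 with 13 to 120.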

Other observations

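Tests on the mitochondrially encoded list other than the length trend, all tests with separate bounds for the ribosomal protein lists, the germ line test and the scan of gene families were chosen only after the results were seen. Removal of the length trend was itself a setting added after the data were seen. For the mitochondrially encoded list, the outcome that would count as length was written before that test. A scan of 145 groups of genes sharing a symbol stem found 9 higher and 16 lower, many of them parts of the fixed lists, and none held with an estimated correlation. All 11 tested asp genes, which encode aspartyl proteases, were above 0, with a median log2 fold change of 0.23 (camera adjusted p = 0.00016; adjusted p = 0.831 with an estimated correlation), among them asp-14 at 0.39 (SE 0.10) and asp-8 at 0.49 (SE 0.17). Of 17 arrd genes, which encode arrestin domain proteins and include arrd-24, 16 were above 0, with a median of 0.21 (camera adjusted p = 0.000524; adjusted p = 0.831 with an estimated correlation); arrd-27 was at 1.89 (SE 0.39) and arrd-8 at 1.06 (SE 0.23). Of 44 transthyretin-related ttr genes 7 were above 0, with a median of -0.29 (camera adjusted p = 1.51e-08; adjusted p = 0.831 with an estimated correlation). With the length trend removed the medians were 0.23, 0.23 and -0.094, and none of the 3 changed direction with quantile normalization or library totals. The egl genes, which share a mutant phenotype and not a sequence family, had 20 of 23 members above 0 (median 0.16, camera adjusted p = 0.00041; adjusted p = 0.506 with an estimated correlation) and were the only group to pass fry (adjusted p = 0.0395). arrd-24 was the only member of the asp and arrd families past the threshold by itself.

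Genes linked to infection differed in direction within the antimicrobial effector list, which did not pass as a whole (camera adjusted p = 0.572). Adjusted over the list alone, dod-24 (0.51, SE 0.098), irg-7 (0.50, SE 0.097), irg-5 (0.81, SE 0.19), spp-8 (0.35, SE 0.10) and ZK6.11 (0.35, SE 0.083) were higher and spp-22 (-0.75, SE 0.18) was lower. None passed over all genes.

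The lower level of the 11 mitochondrially encoded mRNAs is the pattern most tied to a known property of the drug, since nucleoside analogues can inhibit the mitochondrial DNA polymerase. The tables argue against the length trend, because with it removed the median was still -0.49 (camera adjusted p = 8.96e-14). A lower share of mitochondria-rich cells would lower nuclear-encoded oxidative phosphorylation mRNAs alike, if all cells held both kinds in the same ratio. That ratio was not measured, and only on this assumption do the tables argue against such a shift. The difference between the 2 list means, mitochondrially minus nuclear-encoded, was -0.71 with zidovudine relative to DMSO. It was -0.42 without nduo-3 and nduo-6, which had the fewest reads (exact permutation p = 0.0286 for both, the smallest possible). Per library it was 0.36 in zidovudine 2, 0.96 to 1.29 in the other zidovudine libraries and 1.51 to 1.77 with DMSO. Less carry-over of RNA with short poly(A) tails cannot be told apart, since histone mRNAs, most of which lack such tails, differed by -0.044 with a 95% interval of -0.48 to 0.39, and by 0.27 (-0.084 to 0.63) with the length trend removed; the histone list also holds polyadenylated members such as his-24. A loss of mitochondrial DNA or of its transcription may be the reason and stays a hypothesis, as mitochondrial DNA was not measured.

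The lower ribosomal protein mRNAs had different fates once length was considered. For the cytosolic list the length trend of the libraries is a candidate explanation. With the trend removed the median went from -0.14 to 0.024. The list mean's difference went from -0.22 (95% interval -0.66 to 0.22) to 0.0019 (-0.19 to 0.19). The trend was fitted over all genes, these included, so its removal also takes out any drug effect that runs with length. The test therefore cannot tell the trend from such an effect. The same removal raised the median of the histone list from 0.011 to 0.26. For the mitochondrial list the answer depended on the bound. The median went from -0.16 to -0.078, which the bound first written for both lists would have counted as length. By separate bounds set after the values were seen it did not count as length. The list stayed past the threshold (camera adjusted p = 2.06e-05) and the interval of its mean's difference lay below 0 (-0.15 to -0.017). With the trend in place that interval included 0 (-0.35 to 0.0084). As these bounds were set with the values in view, whether the trend is the whole cause stays open. With the trend in place the call was lost with an estimated correlation (camera adjusted p = 0.36). Fewer proliferating germ cells or oocytes would lower their mRNAs too. The medians were -0.0082 for the proliferating and meiotic germ line and 0.084 for oocytes, although the former was lower with the length trend removed (-0.035, camera adjusted p = 0.00980). The sperm list was lower (-0.38, and -0.14 with the length trend removed), so less germ line tissue as a whole stays open. An effect of the drug on these mRNAs stays open and was not separated from library preparation.

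For the number of genes, 1 of 35 splits of the 8 libraries into 4 and 4, the real one, gave 21 genes, and the highest other gave 0. That share, 0.0286, is the smallest that 35 splits can give, and the number of lists was tested alike without adjustment for both. The splits also treat the 8 samples as independent, which the labels do not state. Chance is therefore not excluded for the number of genes. Nor is it excluded for the number of lists. There 10 of the 35 splits, the real one included, gave at least 17 lists and the highest other gave 24.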
